A study of Schizosaccharomyces pombe with 113 samples.

How the data were processed

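The series holds 113 samples of the fission yeast Schizosaccharomyces pombe, and its design text names DNA sequencing to map transposition loci among other assays. Of these, 15 genomic DNA samples with 29 files were used, and the 98 others were not analysed here. These are chromatin, RNA and small RNA samples and 2 DNA samples, of the wild type and of the genotype 1tj1. Cells were grown in rich medium and sequenced either from sonicated DNA on an Illumina instrument or from high molecular weight DNA on an Oxford Nanopore MinION, per the labels' protocols. Samples were grouped by the genotype label, 2tj1 or 3tj1, and by the letter of the strain. This gave 11 strains labelled 2tj1 and 2 labelled 3tj1. Strains G and EL were each sequenced by both methods and counted as 1 strain. Strains are separate cell lines per the labels, each with 1 DNA library per method, so p-values of tests over strains measure the spread between these strains. Those of tests over sites (distance, share, side and orientation) or over reads (single strains) do not.

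The authors deposited, for each sample, the reads that hold the 5' or the 3' end of the long terminal repeat (LTR) of Tj1, with 1 read per line and no other value. The unit is therefore the read itself, and no normalisation was stated. The submitters' processing notes name Novoalign, without a version or a role. The genome build is not given in the sources used here. All coordinates below are 1-based positions on the reference assembly ASM294v3, found by matching the deposited reads to it.

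The LTR ends were defined as the longest string shared by every short read of an end, 20 bases for each, extended by majority to 40 bases. Flanks found in all 8 short-read samples were set apart as shared flanks and matched over up to 24 bases, allowing 2 mismatches in short reads and 7 edits in long reads. Identical short reads were collapsed to 1. Short flanks of at least 15 bases were placed where they matched the genome exactly or else with 1 mismatch. In long reads, LTR ends were found with edlib 1.3.9 allowing 9 edits in 40 bases, each distinct read counting once per sample. Up to 5000 bases of flank were aligned with minimap2 2.31 (map-ont). Flanks of at least 50 bases were kept if the alignment began within 30 bases of the LTR end, and placed at a single position from a mapping quality of 10. Placed junctions within 20 bp (short reads) or 50 bp (long reads) of each other were joined into a site, which needed 2 junctions. In short reads these came from distinct reads, while 1 long read across a copy could give both. The shared copy needed 2 distinct short reads or 1 long read. A flank with several equally good places was assigned only where exactly 1 of them lay at a site found from other reads of the strain. A site was called shared if strains of different letters held it, and strain-specific otherwise.

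Genes came from the annotation of the reference: 171 tRNA genes, 36 5S rRNA genes and 1 gene each for U6, SRP RNA and RNase P RNA, all transcribed by RNA polymerase III (Pol III). Because annotated 5S entries differ in length, positions at 5S genes were also counted from the first base of the 119-base sequence found in entries of the most common length. The rule for naming sites, fixed before the data were examined, was to name every strain-specific site with its nearest tRNA gene and nearest or enclosing gene, and the shared site.

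Distances to tRNA genes were compared with 100000 sets of random nuclear positions by a one-sided permutation test. Shares within 500 bp were compared with the share of nuclear bases within 500 bp by a one-sided exact binomial test, with 95% exact Clopper-Pearson intervals. Side and orientation were tested by two-sided exact binomial tests against equal shares. Sites per strain were compared by a two-sided exact permutation test. Log2 ratios of read numbers, with a pseudocount of 0.5 for junction reads, were tested by two-sided exact sign-flip permutation tests over strains, and each strain by an exact binomial test adjusted by Benjamini-Hochberg. The numbers of reads with the 5' and the 3' LTR end were compared as deposited, without collapsing identical reads. The plan was to sum both LTR ends of each site. The shared copy had no 5' LTR end next to genomic sequence, so the 3' end alone was compared, with the same minimum flank at both sites and an intact 20-base LTR end in long reads.

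Tests of share, side and orientation over all Pol III genes, tests on 5S genes alone and of the difference between read types, and the junction reads of the strains read by both methods and the pairing of 3tj1 with 2tj1 strains, were added after the data were examined, as were the structure of the shared copy, the length and marker genes of the copies and the flanks near centromere 2. Copy length was the distance between the outer LTR ends within a single read. The 1500 bases before the 3' LTR were compared with consensus sequences of up to 25 reads made with mafft 7.526, and markers were named from peptides of common resistance genes found in the translated consensus. Statistics used numpy 2.4.6 and scipy 1.17.1 under Python 3.11.15, and plots used matplotlib 3.10.9.

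The procedure was tested on simulated data. Of 200 insertions at random places with 6 short reads per end, 194 were placed at the right base, 6 were not placed and 0 were placed elsewhere. Of 171 insertions simulated 9 bp upstream of each tRNA gene, 128 (74.9%) were placed, 43 were not placed because both flanks matched several copies, and 0 were placed elsewhere. For 5S genes, 31 of 35 were placed. All 60 insertions simulated with 3 long reads per end and 8% errors were placed within 10 bp, and their 5-bp duplication was measured as 5 bp in 40. On data without an effect, p fell below 0.05 in 4% of 100 runs of the distance test, 1.25% of 400 runs of the share test, 5% of 400 runs of the sign-flip test and 5.25% of 400 runs of the split of 10 values into 6 and 4.

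Short-read samples held 64 to 131 distinct reads and long-read samples 1 to 776. The reads carry no molecular identifiers, so intervals and limits cover counting error only. Alternatives fixed before the data were examined changed the minimum number of reads, the collapsing of reads, the minimum flank, the treatment of flanks with several places, the need for both ends, the joining window, the distance limit, the random positions, the gene class, the LTR end, the read type and the strains included.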

Results

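The DNA samples were sequenced to map where Tj1, an LTR retrotransposon of the related yeast Schizosaccharomyces japonicus, had inserted in Schizosaccharomyces pombe strains. The 15 samples came from 13 strains, 11 labelled 2tj1 (A to K) and 2 labelled 3tj1 (FM and EL). Short reads of 50 bases covered 8 samples (A, D, E, F, G, K, FM and EL), with 36 to 105 reads per sample holding the 3' LTR end and 31 to 118 holding the 5' end. Nanopore reads covered 7 samples (B, C, G, H, I, J and EL), with 1 to 595 reads for the 3' end and 2 to 348 for the 5' end where a file was present. Strain H had a single read. All 1256 reads of the 3' files held the string ATCGGCCTCCGCCGTTGACA and all 956 reads of the 5' files held TGTCAGAGCCAATATACAAC, in the orientation deposited. For short reads this was fixed in advance, as the strings were defined as those that every short read of an end shares. Neither string occurred in the S. pombe reference. The LTR had a median length of 242 bp over 682 complete LTRs in nanopore reads (quartiles 239 and 244).

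All 13 strains held reads of 1 shared copy of Tj1, which the nanopore reads of 7 strains placed in an engineered construct on chromosome I. In the long reads, the 3' LTR end of this copy was followed by AGAGCGGATCCCAGCTGGCTAGCA, which has 0 matches in the genome, and then, after a median of 175 bp, by genomic sequence. The first genomic base was position 4001185 in 162 of the 222 long reads with this junction. On the other side the genome ended at 3995805, so that the construct took the place of 5379 bp (3995806 to 4001184) including Tf2-5, an endogenous LTR retrotransposon (3996423 to 4000424). In 33 reads that spanned it, the construct had a median length of 8809 bp. These reads, the only ones to reach the side at 3995805, came from strains J (20), EL (12) and G (1). All 33 held 1 LTR start and 1 LTR end, so in these strains the shared copy carried a single complete LTR, at its 3' side. In B, C, H and I, 0 reads reached the side at 3995805, and strains with short reads alone have no spanning reads. A segment of ade6, a gene of adenine synthesis whose loss gives red colonies, was found in 15 reads (chromosome III, 1316336 to 1317995).

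Beyond the shared copy, 12 strain-specific sites with at least 2 junctions were found, and each of these lay at most 12 bp from a Pol III gene. Of these, 8 lay upstream of tRNA genes and 4 at the start of 5S rRNA genes. The median distance to the nearest tRNA gene was 11 bp (range 5 to 80672, n = 12), against 37087 bp at random positions (permutation test, one-sided, p = 1e-05, the smallest that 100000 sets can give). Within 500 bp of a tRNA gene lay 8 of 12 sites (66.7%, exact 95% interval 34.9 to 90.1), a region that makes up 1.23% of the nuclear genome (54.4-fold, exact binomial test, one-sided, p = 2.42e-13). The 4 other sites, 24177 to 80672 bp from a tRNA gene, lay at 5S genes, which have 0.334% of the genome within 500 bp (exact binomial p = 5.99e-08). Counting every Pol III class, 12 of 12 sites lay within 500 bp (exact interval 73.5 to 100), at a median distance of 8.5 bp, against 1.54% of the genome (exact binomial p = 1.84e-22). Counts of sites depended on the reads accepted. A minimum of 1 read gave 21 sites, the 9 added ones all in strain EL and 0 of them within 500 bp of a Pol III gene, keeping flanks at every equally good place gave 24, and short-read libraries alone gave 6. The map of sites on the chromosomes shows 7 on chromosome I, 2 on II and 3 on III.

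**Figure D1:**
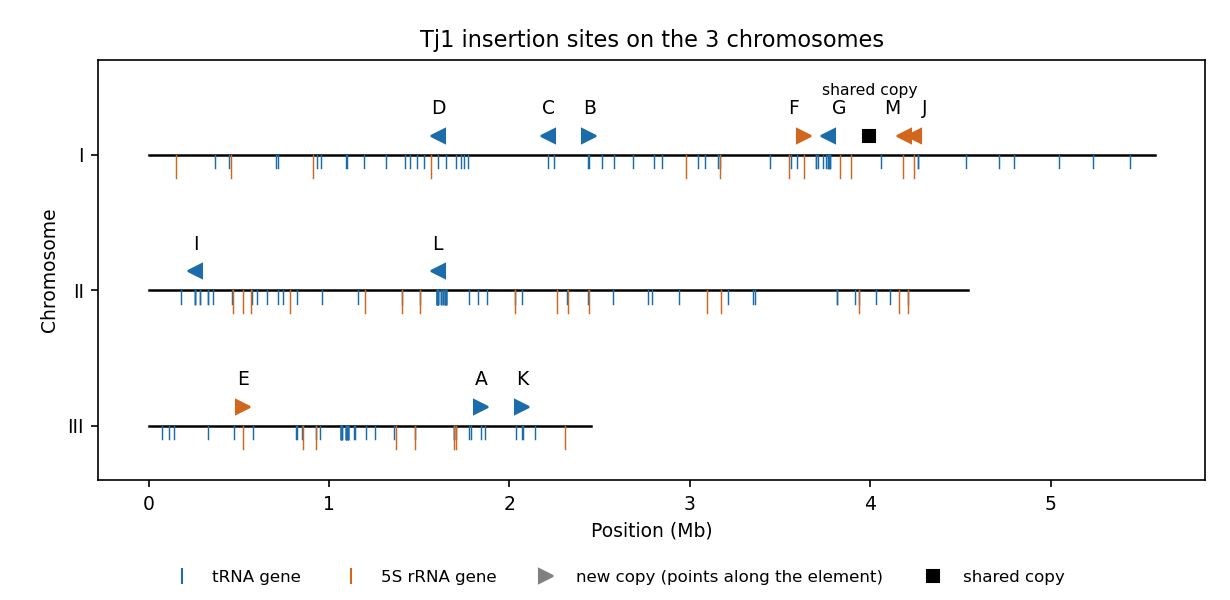
Positions of Tj1 copies on chromosomes I, II and III of the reference (position in Mb); triangles are the 12 strain-specific sites, named by letter, coloured by the class of the nearest Pol III gene and pointing along the element, and the square is the shared copy. Ticks under each line are the 171 tRNA genes (short) and 36 5S rRNA genes (long), and each triangle stands over such a tick.

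The tRNA genes next to new copies served 7 different amino acids. In strain A the element lay at 1844634 on chromosome III, 5 bp upstream of the tRNA-His gene SPCTRNAHIS.04. In strain K it lay at 2072069 to 2072073 on the same chromosome, 11 bp upstream of the tRNA-Ser gene SPCTRNASER.13. Chromosome I held the copies of strain B at 2441954 to 2441956, 9 bp upstream of the tRNA-Lys gene SPATRNALYS.03, and of strain C at 2214819 to 2214823, 9 bp upstream of the tRNA-Val gene SPATRNAVAL.03. It also held those of strain D at 1603380 to 1603384, 8 bp upstream of the tRNA-Thr gene SPATRNATHR.01, and of strain G at 3765510 to 3765514, 9 bp upstream of the tRNA-Glu gene SPATRNAGLU.03. On chromosome II, strain I had its copy at 258926 to 258930, 11 bp upstream of the tRNA-Gln gene SPBTRNAGLN.03. The second new copy of strain EL, called L here, lay on the same chromosome at 1601570 to 1601574, 12 bp upstream of the tRNA-Glu gene SPBTRNAGLU.06. Each range gives the bases that belong to both flanks. Distances were counted from the genomic base next to the 3' LTR end, which is the end of the range farther from the gene. Each site rested on 3 to 81 junction reads at its 5' end and 3 to 113 at its 3' end, summed over the strains that held it.

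At the 4 5S genes, the genomic base next to the 3' LTR end lay 4 or 5 bp upstream of the first base of the 119-base 5S sequence. At sites E, J and M, 4 bp upstream, the 5 bases shared by both flanks included that first base. Strain E had its copy on chromosome III at 523313 to 523317, next to SPRRNA.24. The copies of strains F (3634366 to 3634370, SPRRNA.16) and J (4240968 to 4240972, SPRRNA.20) and the second new copy of strain FM, called M (4184473 to 4184477, SPRRNA.19), lay on chromosome I. Sites E and M lay inside the annotated 5S entries, which begin further upstream than the 119-base sequence.

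All 8 copies at tRNA genes lay on the upstream side and in the transcriptional direction of the gene, at a median of 9 bp (range 5 to 12). Both counts, 8 of 8 upstream and 8 of 8 in the same orientation, had an exact binomial p of 0.00781 (two-sided). Over all Pol III genes, 12 of 12 copies had the orientation of the gene (exact binomial p = 0.000488). Of these, 10 lay upstream of the annotated gene, 0 downstream and 2 inside the longer 5S entries.

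**Figure D2:**
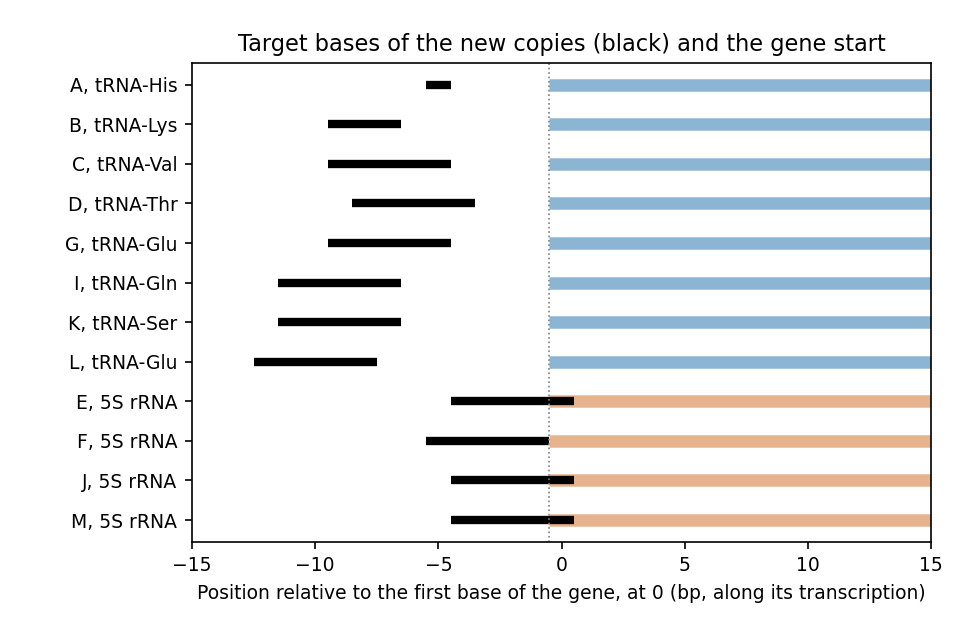
Bases that belong to both flanks of each new copy (black) relative to the first base of the tRNA gene (blue) or 119-base 5S sequence (orange), in bp along the direction of transcription, with 1 line per site. Sites at tRNA genes begin 5 to 12 bp upstream and sites at 5S genes 4 or 5 bp upstream.

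No new copy lay in a protein-coding gene, although such genes cover 76.7% of nuclear bases. The nearest coding gene was 326 to 13785 bp away (median 534). For the copy of strain C this was chp1, which encodes a chromodomain protein of heterochromatin, at 478 bp, and this copy also lay in an exon of the long non-coding RNA SPNCRNA.2990. For strain A it was set11, a ribosomal protein methyltransferase gene, at 326 bp, and for M it was mal2, a kinetochore protein gene, at 805 bp. Sites G and L lay 1091 and 1199 bp from annotated centromeric transcripts, and 0 sites lay within 50000 bp of a chromosome end. The mating-type genes were at least 512649 bp away from every site.

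Strains labelled 3tj1 held 3 copies and strains labelled 2tj1 held 2, with 1 exception. The mean number of sites, including the shared one, was 1.91 ± 0.30 (SD, n = 11) in 2tj1 and 3 ± 0 (SD, n = 2) in 3tj1 strains (exact permutation test, two-sided, p = 0.0128, the smallest that 78 splits can give). The numbers in the labels match these counts, so if they state the number of Tj1 copies, the grouping fixed the difference in advance. The p-value is then no separate evidence for it. The permutation test also takes the strains as independent, although EL and FM each share a new copy with a 2tj1 strain (E and F). Paired with E and F, both had 1 site more (exact sign-flip permutation p = 0.5, the smallest that 2 pairs can give). The exception was strain H, whose single read of 9763 bases came from the shared copy. A count of 0 of 1 reads at a new site allows a share of up to 97.5%, so a new copy was not detectable at this depth. Among strains with short reads only, the same comparison had 5 strains against 1 (exact permutation p = 0.167, the smallest possible). Leaving out either FM or EL gave p = 0.167 in the exact permutation test, where 0.0833 is the smallest possible, because setting strain H apart gives as large a difference.

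The 3tj1 strains kept the new copy of the 2tj1 strain whose letter they share. The site of strain F was found again in FM and that of strain E in EL, each with a difference of 0 bp, and no other 2tj1 site was found in either. The remaining new copies of FM and EL were M and L. In the strains sequenced by both methods, short and long reads gave the same most frequent bases for site G and for both sites of EL, with differences of 0 bp. At site G this rested on little. Its 2 long 5' junctions lay at different bases, of which the lower position was taken, and 1 long junction gave the 3' base. However, the short reads alone could not place 2 of these sites, because both flanks matched a repeated sequence. The 12 placed short reads of strain G fitted chromosome I at 3765510 to 3765514 and, in the opposite orientation, at 3776759 to 3776763. The 17 short reads of L fitted chromosome II at 1601570 to 1601574 and at 1646908 to 1646912. The choice of place for site G therefore rested on 2 junctions in long reads, as the other of its 3 long junctions also fitted several places. Several places also fitted 108 of 170 long junctions at L, 13 of 20 junctions at M and 6 of 15 at A. At site F they fitted 7 of 13 junctions in strain F and 8 of 17 in FM. The remaining junctions counted here had 1 place each.

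Both flanks of a new copy overlapped on the genome by 5 bp at 7 of the 8 sites with short reads, as left by the target site duplication of LTR retrotransposons. Strain A was the exception with 1 bp, and its 3' flanks also matched a tRNA-His gene on chromosome II. With all read types, 10 of 12 sites had 5 bp and strain B had 3 bp, measured on 3 nanopore junctions per end. The 10 duplicated sequences of 5 bp were 9 different ones, with A or T at 36 of 50 bases (72%). The share of A or T elsewhere in the genome was not computed, so this value shows no preference.

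If new and shared copy are each present once per haploid genome, their junctions should yield equal numbers of reads. Over the 10 2tj1 strains with both sites, the mean log2 ratio of 3' junction reads at the new site to the shared site was 0.06 ± 0.88 (SD, n = 10, exact sign-flip permutation test, two-sided, p = 0.838), and no difference was detectable. The strains differed by read type. With short reads the new site had fewer reads in 6 of 6 strains, 34 against 51 in total (mean −0.54 ± 0.37, SD, n = 6, exact permutation p = 0.0312, the smallest possible). With nanopore reads it had more in 4 of 4 strains, 66 against 39 (mean 0.95 ± 0.57, SD, n = 4, exact permutation p = 0.125, the smallest possible). The difference between read types was 1.49 (exact permutation test, two-sided, p = 0.00476). Strains entered only if a new site had been found, which needed 2 junctions, while 1 long read sufficed for the shared copy. Nanopore strains with very few reads at a new site were thus left out in advance, as was H with 0 against 1. The 4 of 4 and the difference between read types are not free of this selection. In strain EL, read by both methods, the ratio was also higher in nanopore reads, with 93 (L) and 81 (E) against 136 at the shared site (−0.55 and −0.74), than in short reads, with 7 and 4 against 14 (−0.95 and −1.69), but all 4 values lay below 0. Strain G had 5 against 7 short reads and 0 against 2 nanopore reads, too few to compare the methods. The sign of the pooled mean depended on which strains and read types were included. Single strains had an adjusted exact binomial p of 0.314 or above, the lowest in J with 54 against 33 reads (unadjusted exact p = 0.0314).

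**Figure D3:**
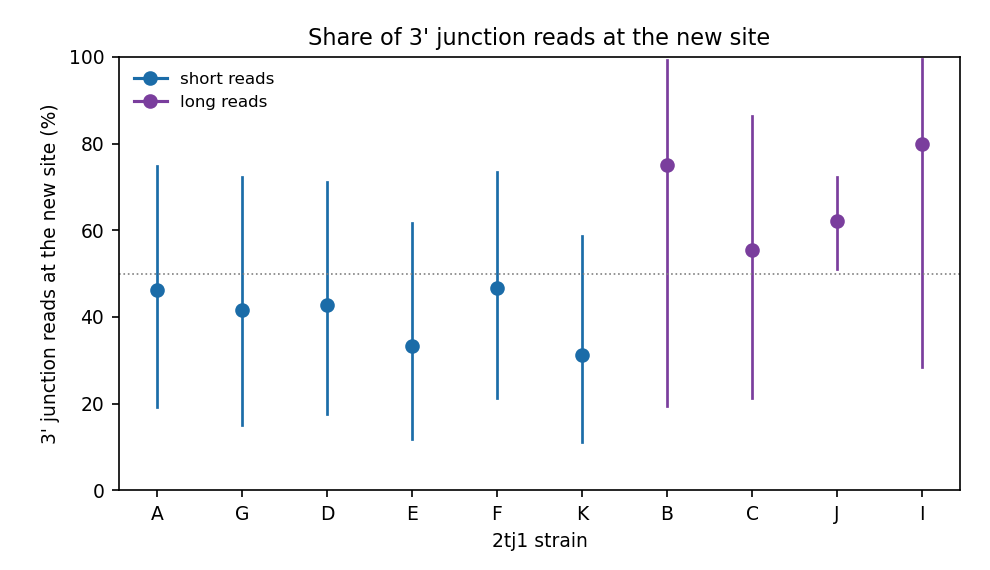
Percentage of 3' junction reads that came from the new site rather than the shared site in each of 10 2tj1 strains; points are single strains, vertical lines exact 95% binomial intervals (counting error only), and the dotted line marks 50%. The 6 strains with short reads lie below 50% and the 4 with nanopore reads above it, from 31.2% (K) to 80% (I).

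Whether reads with the 5' LTR end were fewer than those with the 3' end depended on how identical short reads were counted. With all reads as deposited, the mean log2 ratio was −0.12 ± 0.39 (SD, n = 8, exact sign-flip permutation p = 0.391) in short-read samples, 489 against 512 reads. In long-read samples it was −0.47 ± 0.77 (SD, n = 6, exact sign-flip permutation p = 0.219), 467 against 743 reads. Collapsing identical short reads, as was done for the sites, gave −0.42 (n = 8, exact permutation p = 0.0156).

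The 7 new copies covered by nanopore reads (B, C, G, I, J, E and L) had an LTR at both ends and carried another resistance gene than the shared copy. Neither was measured for A, D, F, K and M, which had only short reads. Read through by single nanopore reads, the copies had median lengths of 5859 bp in strain B (3 reads), 5887 bp in C (4 reads), 5876.5 bp in I (4 reads), 5892 bp in J (41 reads) and 5937 bp at site E of strain EL (12 reads), with 5953 bp in the single read of G. Copy L was longer, at 6155 bp (13 reads, range 6104 to 6177). In the 1500 bases before the 3' LTR, the shared copy held a nourseothricin-type resistance gene in 81 of 81 reads from 7 strains. The 7 new copies held this gene in 0 of 131 reads. Instead, those of B, C, G, I, J and E held a kanamycin-type gene in every read tested (3, 5, 1, 4, 54 and 30 reads), and copy L held a hygromycin-type gene in 32 of 34 reads, the other 2 being of the kanamycin type. In the consensus sequences of strains J and EL these genes ran antisense to the element. The names rest on short peptide stretches found there without an edit, 2 of 3 for the kanamycin type and 2 of 4 for the hygromycin type. For the nourseothricin type these were 4 of 4 in J and 2 of 4 in EL.

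Copy L in strain EL lay next to centromere 2 in a region that differed from the reference. The 24 5' flanks of at least 2000 bases counted along the reference all began at 1601570. Of these, 21 were placed over at least 90% of their length, reaching position 1655272 at most. The longest, of 61383 bases, was placed only up to 1617837. Because these 24 were counted as following the reference, they give no share to set against the 3' flanks. Of 31 3' flanks with at least 2000 bases, 0 ran straight on along the reference. In 26 of them the sequence went on, after a median of 513.5 bases, at position 1619264 and from there down the chromosome, as far as 1577543. The new position was exact in 25 reads. The 5 other flanks followed neither course. The segment of 17695 bp between the insertion and this position holds 1 assembly gap in the reference (1616571 to 1616670).

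**Figure D4:**
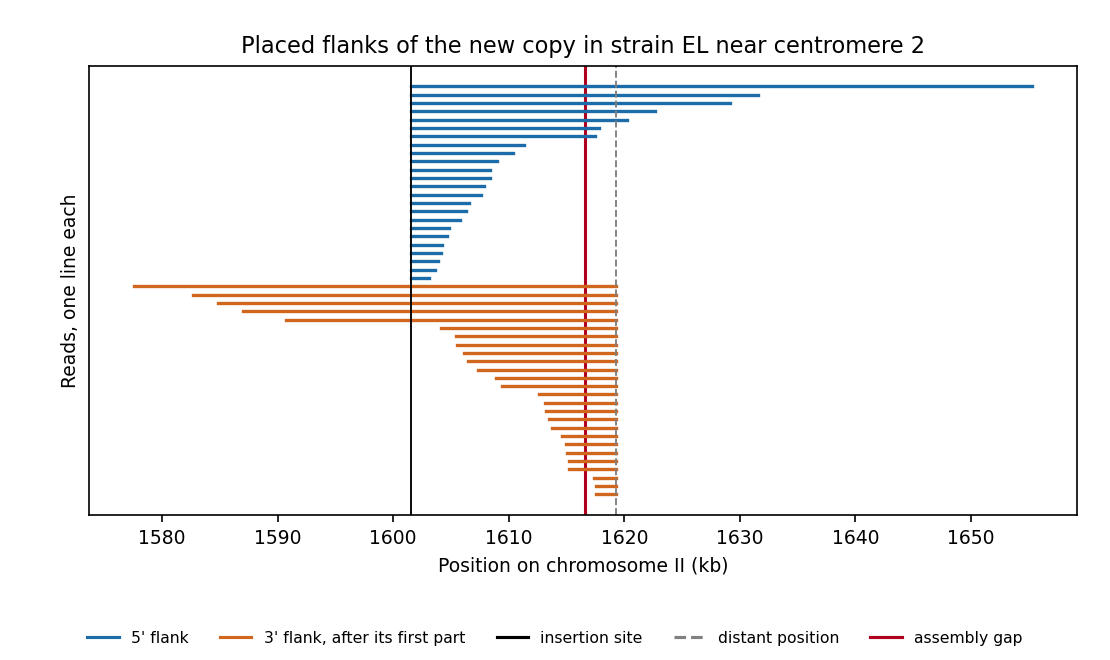
Placed flanks of copy L in strain EL on chromosome II (kb), with 1 horizontal line per nanopore read; blue lines are 24 5' flanks, orange lines the 26 3' flanks drawn from the distant position on, the solid vertical line the insertion site, the dashed line position 1619264 and the red line the assembly gap. The 3' flanks share their right end at the dashed line, and the longest cross the insertion site.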

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

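The tests in this part were all chosen after the results were seen. Single values were compared with the others in 14 groups of samples, by Dixon's ratio of gap to range. In 5 groups a sample lay far from the rest. The chance rate of 1 in 20 assumes normally distributed values and is no guide here. In the flagged groups of overlaps and sites per strain all other values were equal, so any single deviation is flagged. The flagged 5' and 3' read numbers of strain J partly come from the same reads.

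The overlap of the flanks was 1 bp in strain A, far from the 5 bp in each of the other 5 short-read 2tj1 strains. The 3' flanks of this strain match 2 tRNA-His genes, the assigned one and SPBTRNAHIS.01 on chromosome II at 464233, so separate insertions at both genes, each seen at 1 end only, could give a false overlap. Ends missed by chance are argued against, since 0 of 9 placed 5' reads lay at the second gene (exact binomial probability 3.05e-05 that both insertions show 1 end each) and 11 of 11 other sites had at least 3 reads at both ends. Sequencing errors next to the LTR end are argued against by the reads themselves, since 15 of 15 placed reads began at the same base of their end. Copies that each lack an end stay open, because 0 of the 6 placed 3' reads match the assigned gene alone, as does a short insertion or deletion of this strain against the reference, because 0 reads of the strain cross the site without the element.

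The overlap of 3 bp in strain B stood apart from the 5 bp of the 3 other long-read 2tj1 strains. It was measured on 3 nanopore junctions per end, a depth at which 40 of 60 simulated 5-bp duplications were measured as 5 bp.

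Strain J had 123 nanopore reads with the 3' LTR end and 101 with the 5' end, against 1 to 12 and 2 to 7 in the other 2tj1 nanopore samples. Strain H had 1 insertion site against 2 in the other long-read 2tj1 strains, from a single read. The log2 ratio of junction reads at the new site to the shared site differed by 1.49 between nanopore and short reads, means of 0.95 (n = 4) and −0.54 (n = 6). Each strain entered this comparison with 1 method, so strain and method are confounded in it. Nanopore strains without a site found from at least 2 junctions, such as H, could not enter it. In EL, read by both methods, the log2 ratio was also higher in nanopore than in short reads (−0.55 against −0.95 at L, −0.74 against −1.69 at E) but below 0 in both. Strain G, with 0 against 2 nanopore reads and 5 against 7 short reads, had too few to compare the methods.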

How the results depend on the processing

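The following were chosen after the data were seen: leaving out H, FM or EL and pairing strains for the sites per strain; single read types, LTR ends with errors and the inner flank for the junction reads; any Pol III class for share, side and orientation; short-read libraries alone for the number of sites; and collapsed 5' and 3' reads. Of 64 alternatives over 11 results, 47 left the result the same. For results with a test this meant the same direction and side of the threshold. Counts and shares without a test had to stay within set limits of the main value, such as 1 SD for the mean sites per strain. The 47 included every alternative of the distance to tRNA genes, the share near them, the side and the orientation. Several of these could not change the result. Every site lay at most 12 bp or at least 24177 bp from a tRNA gene, so the distance limits all gave the same sites. The settings that add sites were not applied to the distance, share, side or orientation. The share near tRNA genes was 63.6% to 72.7% when each strain was left out, though leaving out E, F or H removed no site. Strain-specific sites numbered 21 with a minimum of 1 read (2.77 sites per strain), the 9 added sites all being in EL with 0 near a Pol III gene. Keeping flanks at every equally good place gave 24 sites (3.15 per strain), the same 12 and 12 repeats of them near Pol III genes. Short-read libraries alone gave 6, because B, C, I and J have no short reads and those of G and L could not be placed. The difference of 3tj1 over 2tj1 strains, 1.09 sites, was 1 with short-read strains alone (exact permutation p = 0.167, the smallest possible) and 1.09 without FM or without EL (exact permutation p = 0.167, where 0.0833 is possible, since setting H apart gives as large a difference). With E paired with EL and F with FM it was 1 (exact permutation p = 0.5, the smallest that 2 pairs allow). If the numbers in the labels state Tj1 copies, the grouping fixed this difference in advance. The mean log2 ratio of junction reads, 0.06, changed sign with all reads counted (−0.0030), with the 5' end (−0.16) or the mean of both ends (−0.0035) of the new site, and with short reads alone (−0.54, exact permutation p = 0.0312); leaving out each strain gave −0.11 to 0.18, below 0 without B, J or I. The cause of these changes was not tested. The 5' to 3' ratio of short reads passed the threshold once identical reads were collapsed (−0.42, exact permutation p = 0.0156). Depth limits strain H and the per-strain comparison of junction reads.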

Other observations

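The tests in this part were all chosen after the results were seen. A preference for 5S over tRNA genes was not detectable with 12 sites. The new copies took 4 5S genes among 12 targets (33.3%), against 36 of 207 genes of both classes (17.4%, exact binomial test, two-sided, p = 0.141). Among the 8 tRNA targets, 2 (25%) lay within 2000 bp of a centromeric transcript, against 35 of 171 tRNA genes (20.5%, exact binomial p = 0.670). Genes for tRNA-Glu, of which the genome has 10, were hit at 2 places, both near centromeres, and no tRNA gene was hit in more than 1 strain.

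The resistance gene of the 7 new copies with nanopore reads differed from that of the shared copy, and that of the 5 others was not measured. If these copies had been made from the shared copy as it now stands, they would carry its nourseothricin-type gene, which 0 of 131 reads did. Nanopore errors that make the markers hard to tell apart are argued against by the distance between markers, a median of 593 edits between the best and the next. The smallest distances, 22 and 23 edits, were in EL, so single reads there were less clear. Reads of J and EL were compared with consensus sequences from their own strains, which builds in part of the distance. In B, C, G, H and I, which gave no consensus, the distance was at least 305 edits. A candidate explanation is that the donor of the copies was another element, or that the marker of the shared copy was exchanged later, and none of the reads tests either. The labels also name strains called 1tj1neo, which were not analysed here, so a change of marker between strains was not tested.

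The 3' flanks of copy L in strain EL went on at a distant position near centromere 2. Chimeric nanopore reads would join at scattered bases, and 25 of all 31 3' flanks with at least 2000 bases went on at exactly the same base. An error of the reference, shared by other strains, and a rearrangement of this strain cannot be told apart, because 0 long reads of other strains were placed within 50000 bp of the site. Either may account for flanks that leave the reference there.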
